A study of Homo sapiens with 12 samples.

How the data were processed

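The deposited files are HOMER peak lists, 1 per ChIP library, for 8 of 12 samples: H3K4me3 and H3K27ac in a METTL3 control and a METTL3 KD stable line of HEC-1-A, with 2 libraries each. The 4 input samples have no file used here; input tags were read from the columns of the peak lists. Per the submitters' processing notes, the authors used CASAVA, Trimmomatic 0.38, Bowtie 1.2.2 and HOMER on hg38, with the parameters not stated. Per the labels' protocols, chromatin was prepared with a kit for histone ChIP with added spike-in chromatin and spike-in antibody. The labels do not say that the libraries of a pair came from separate cultures.

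Per the file headers, each list holds peaks of 1000 bp called in 1 library against its input. The H3K4me3 lists give total tags as whole counts per the file headers. In the H3K27ac lists, per the file headers, total tags are a signal scaled to the depth of the input, and control tags are a signal as well (scaled to the ChIP library in the H3K4me3 lists). The normalized tag count is a signal that the authors' peak caller scaled to a common library total, taken here as the caller's default, since the files do not state it. The findPeaks score, the ratio or fold change over input and over the local clonal expectation, and the p-value against input are, per the file headers, as the authors' caller gave them; the lowest fold change over input in the files was 2. Library totals were derived from the ratio of total tags to normalized tag counts at that default: 32582000, 32045000, 32093000 and 30752000 for H3K4me3 (control 1 and 2, KD 1 and 2) and 35746000, 36820000, 35976000 and 35375000 for H3K27ac. Scaled H3K27ac tags were multiples of 1 step per library, and 99.7% to 100% of them gave whole tags within 0.05 tags. In tests of KD against control these recovered tags were used in alternatives only. They also served for shares of tags in peaks, the simulation and the comparison of the libraries of a pair.

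Peaks of the 4 libraries of a mark were merged where they overlapped by at least 1 bp, and regions with a peak in all 4 were tested, since a library without a peak has an unknown level. H3K4me3 counts were tested with edgeR 4.0.16 (quasi-likelihood, robust) with the library total as library size. The design chosen before the data were examined named the same test for H3K27ac, with limma-trend as the fallback if the column did not hold whole counts. The fallback was needed, so H3K27ac was tested with limma 3.58.1 (limma-trend) on log2(normalized tag count + 1), and its fold changes are on that scale, which understates changes at low values. Calls are at a Benjamini-Hochberg adjusted p of 0.05. TMM factors, DESeq2 1.42.0, a minimum mean of 50 tags, tags per kb, 1 peak per library and region, an 8-fold threshold over input, a pseudocount of 10, the replicate number as a block and leaving out each library were set as alternatives before the data were examined. Scaling by fly tags, an input correction in windows of 10 Mb with at least 400 input tags, leaving out chromosomes 9 and 21, edgeR on recovered H3K27ac tags and a distance of 5 kb to the other line's peaks were added after the data were seen.

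Genes were taken from a RefSeq annotation of the GRCh38.p14 assembly, which matches hg38. It gives no strand, so the planned use of the 5' end was not possible. A promoter region is instead a shared region within 1 kb of either end of a protein-coding gene, the one with most tags where there were several, and for H3K27ac it also had to overlap an H3K4me3 peak; a distal region lies farther from every such end. Regions at the 3' end of a gene can therefore be counted as promoters. The 21 gene lists hold 495 names, all matched to the annotation, and were fixed before the data were examined. They were tested with camera (preset correlation 0.01 and estimated) and fry, and placed among 10000 random lists matched on signal. A gene's call within a list was adjusted over all regions tested and, separately, over the list alone. Lists count genes, and 3 HOX genes share 1 region in each mark, as do 2 epithelial genes.

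The rule for named genes, set beforehand, took for each mark the 7 rises and 7 falls of largest log2 fold change among called promoter regions at or above the median signal, the 4 gained and 4 lost promoters of highest signal, the 4 distal H3K27ac regions of smallest p per direction, the 3 members of smallest p in each list, and METTL3. Genes outside it are said to be chosen after their values were seen. A region near the ends of several genes may be given under 1 of them.

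On simulated counts for the 17328 H3K4me3 regions with 200 changed, the fit recovered 83% of changes of 0.5 (log2) and 99% of changes of 1.0, and 1.6% of its calls were false. For the 30135 H3K27ac regions it recovered 57% and 96%, and 15.9% of calls were false (29 calls), so single H3K27ac calls are less certain. The simulation had few changed regions and no shared shift, so its false shares do not carry over to the data as rates. With 2 near-identical libraries per line, p-values measure only the spread between these libraries, which may be technical. Tags are not independent molecules, so intervals cover counting error only.

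Left out were 22 H3K27ac peaks on chromosome Y and 132 H3K4me3 peaks on fly sequences, of which only counts are given. The results at 3 single promoters are not reported here. R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.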

Results

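Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured 2 histone marks in HEC-1-A, a human endometrial adenocarcinoma cell line. The marks were H3K4me3, trimethylation of lysine 4 of histone H3, which is found mainly at active promoters, and H3K27ac, acetylation of lysine 27, which is found at active promoters and enhancers. Both were measured in 2 stable lines, a METTL3 control line and a METTL3 knockdown (KD) line, with 2 libraries per line and mark, 8 in all. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA, and the comparison asks how active histone marks differ when it is depleted. The 4 H3K4me3 libraries held 30752000 to 32582000 mapped tags and the 4 H3K27ac libraries 35375000 to 36820000, as derived from the files. Values are normalized tag counts of peak regions on the hg38 build, scaled to the library total.

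The 2 libraries of each line and mark differed by less than the sampling noise and were counted as 1 sample. The chi-square per degree of freedom between their tag counts was 0.827 (control) and 0.754 (KD) for H3K4me3, and 0.876 and 0.884 for H3K27ac. Between the lines it was 4.41 to 5.82. It was taken over shared regions with 1 closely aligned peak per library, 12902 for H3K4me3 and 11327 for H3K27ac. For H3K27ac it used recovered tags. Each line is therefore 1 sample per mark (n = 1), the differences below have no replicate check, and the tests compare these libraries, not the conditions. Every group value is the mean of the pair of libraries, and every ± is the standard error of the fitted log2 fold change (KD vs control), which covers the spread between these libraries only.

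METTL3 itself carried both marks in every library. Its H3K4me3 region (chromosome 14, 21510324 to 21511379) had normalized tag counts of 325.6 and 316.1 in the control libraries and 376.7 and 372.7 in the KD libraries. The log2 fold change was 0.22 ± 0.04, and -0.07 and no longer called once the shift of most regions described below was removed. Its H3K27ac region had 55.1 and 66.0 in control and 50.6 and 50.6 in KD. The log2 fold change was -0.25 ± 0.10, and -0.11, not called, after that removal. Marks on the gene do not measure a knockdown that acts on its RNA, so these values do not check the labels.

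H3K4me3 was higher in the KD libraries in most of the regions with a peak in all 4. Among promoters with strong signal, it rose at IGFBP3, which encodes a binding protein of insulin-like growth factors, from 255 to 421 normalized tags (log2 fold change 0.73 ± 0.04). At THRB, the thyroid hormone receptor beta gene, it went from 293 to 483 (0.72 ± 0.04). ANXA1, encoding the phospholipid-binding protein annexin A1, rose by 0.79 ± 0.04 and QNG1 by 0.76 ± 0.04. The falls among strong promoters were small and all on chromosome 5. They were -0.15 ± 0.03 at the promoter shared by NSUN2, an RNA cytosine methyltransferase gene, and SRD5A1, a steroid reductase gene. ICE1 had -0.13 ± 0.04, and the promoter of the chaperonin gene CCT5 and ATPSCKMT had -0.10 ± 0.03.

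Of 17328 regions with an H3K4me3 peak in all 4 libraries, 14297 were higher and 306 lower in KD by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median log2 fold change was 0.29. With TMM factors, which remove this shift, 3193 regions were higher and 2040 lower, and DESeq2 with its own size factors called 1468 and 398. Among 11091 protein-coding genes with a promoter region, 10593 were higher and 74 lower, or 1693 and 1395 once the shift was removed. Gene counts given below as relative to the shift come from this TMM fit. Peaks held 32.2% and 32.7% of all tags in the control libraries and 40.7% and 40.9% in the KD libraries, and the lists held 19440 and 19459 peaks against 22824 and 22714. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333.

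**Figure D1:**
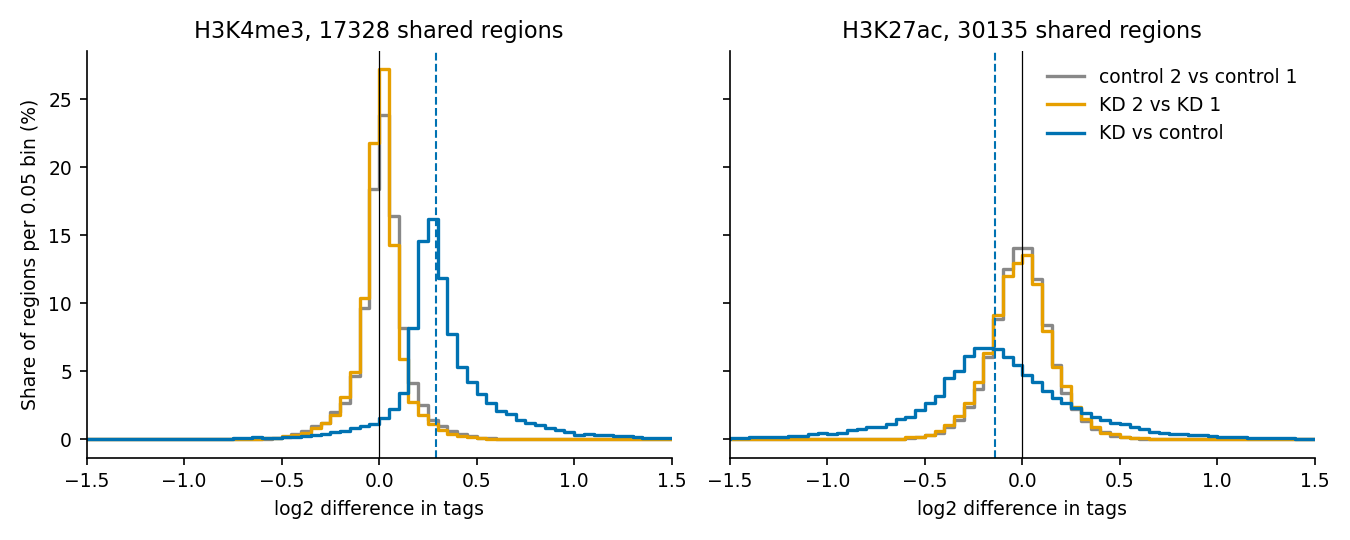
Distribution of log2 differences in tags over regions with a peak in all 4 libraries, for H3K4me3 (17328 regions) and H3K27ac (30135 regions), between the lines and between the libraries of a pair; the dashed line marks the median of KD vs control. The KD vs control curve is shifted to 0.29 for H3K4me3 and to -0.14 for H3K27ac, and is wider than the curves within a line.

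The 3 tallest H3K4me3 rises among strong promoters depended on where peaks were placed. The regions of TOB2 (342 to 839 normalized tags, log2 fold change 1.29 ± 0.03), of IKBIP and APAF1 (334 to 787, 1.23 ± 0.03), and of UMAD1 (288 to 667, 1.21 ± 0.03) each held 1 peak in the control libraries and 2 in the KD libraries, so the KD value sums a second peak. They were the 3 shared H3K4me3 regions in which the lines differed in this way. ANXA1 and QNG1 lie on chromosome 9 beyond 60 Mb, where input tags were also higher in KD, and their log2 fold changes were 0.43 and 0.41 after correction for input. THRB, on chromosome 3, went to 0.59 with the correction, and IGFBP3 stayed at 0.73. The values at NSUN2 and ICE1 became -0.01 and 0.01 with that correction, and that at CCT5 was -0.12. The correction is made per window, and CCT5 lies in a different window from NSUN2 and ICE1. Whether the fall at CCT5 would remain with other window borders was not tested.

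With total-tag scaling no fixed gene list passed camera, a test of a list against other genes, for H3K4me3 (adjusted p = 0.0734 for the interferon list, and 0.7755 with an estimated correlation). The percentiles given below come from 10000 random lists matched on signal, which ignore correlation between genes. Interferon response genes had a median log2 fold change 0.25 above that of all promoters, at the 99.97th percentile. Of 20 measured genes 11 rose and 2 fell relative to the shift. TLR3, a sensor of double-stranded RNA, went from 143 to 258 normalized tags (0.86 ± 0.06). OAS3, an oligoadenylate synthetase gene, went from 188 to 295 (0.65 ± 0.05), and MX1, an antiviral GTPase gene on chromosome 21, from 109 to 188 (0.79 ± 0.06, or 0.46 after input correction). Cell cycle and replication genes were 0.04 above all promoters, at the 99.81st percentile, with 5 of 30 higher and 0 lower relative to the shift. They included E2F2 (193 to 338, 0.81 ± 0.05), CCNE1 (100 to 172, 0.78 ± 0.07) and CCNE2 (0.46 ± 0.04), which encode a transcription factor and cyclins of S-phase entry. Of 9 mesenchymal genes, 5 rose and 1 fell relative to the shift (94.28th percentile). CDH2, encoding N-cadherin, went from 49.2 to 128 (1.37 ± 0.09), and the repressors SNAI1 and SNAI2 rose by 0.88 ± 0.08 and 0.67 ± 0.06. Among 13 targets of transforming growth factor and WNT signalling, 5 rose and 0 fell relative to the shift (85.68th percentile). The WNT antagonist DKK1 went from 42.6 to 120 (1.49 ± 0.09), SP5 from 31.2 to 66.1 (1.08 ± 0.12) and SMAD6 from 210 to 320 (0.60 ± 0.05).

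Other lists split or followed the shift. The log2 fold changes named are those of members with small p before the shift is removed, so most are rises. Of 14 inflammatory and NF-kB target genes, 3 rose and 2 fell relative to it (4.58th percentile). The chemokine gene CXCL1 went from 89.0 to 178 (1.00 ± 0.07) and the adhesion gene ICAM1 rose by 0.71 ± 0.06. A region at an end of both ACAT2 and SOD2, which encodes mitochondrial superoxide dismutase, fell from 98.1 to 54.6 (-0.85 ± 0.09). Without strand, which of the 2 genes has its promoter there is not known. Of 17 HOX cluster genes, 5 rose and 2 fell (84.25th percentile), with HOXB9 at 0.85 ± 0.06, HOXA10 at 0.63 ± 0.06 and HOXB4 at 0.46 ± 0.04. Endometrial and Mullerian duct genes had 4 higher and 4 lower of 10 (80.66th percentile), with the transcription factor genes PAX2 at 1.07 ± 0.11 and MSX2 at 0.58 ± 0.05. Epithelial genes had 3 higher and 6 lower of 21 (4.14th percentile), with ELF3 at 0.47 ± 0.05, ESRP1 at 0.44 ± 0.04 and KRT7 at 0.37 ± 0.04, the last not called relative to the shift. Among the 6 lower were CLDN4 (-0.24 relative to the shift) and EPCAM (-0.164), chosen after their values were seen. Glycolysis and hypoxia genes had 2 higher and 5 lower of 19 (6.55th percentile), with PFKL, on chromosome 21, at 0.68 ± 0.05 and 0.35 after input correction. Pluripotency and early embryo genes had 2 higher and 0 lower of 5 (78.44th percentile, or 59.03 after input correction), namely TFCP2L1 (0.92 ± 0.09) and KLF4 (0.63 ± 0.04, or 0.19 after input correction). Immediate-early genes had 4 higher and 6 lower of 18 (28.43rd percentile) and cholesterol synthesis genes 4 and 3 of 22 (49.42nd percentile).

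Most enzymes tied to the marks and to m6A were not called relative to the shift. Relative to it, 1 of 18 H3K4 methylation genes was higher and 0 lower (82.75th percentile). It was WDR5, on chromosome 9, at 0.43 ± 0.03 and 0.002 after input correction. Of 15 H3K27 acetylation and methylation genes, 2 were higher and 1 lower (40.14th percentile), with BRD3 at 0.63 ± 0.04 and 0.21 after correction. Of 19 m6A writers, erasers and readers, 2 were higher and 4 lower (96.65th percentile, or 80.41 after input correction). IGF2BP3 had 0.45 ± 0.04 and RBM15B 0.44 ± 0.04. PI3K-AKT-mTOR genes had 4 higher and 5 lower of 25 (15.48th percentile, or 1.215 after input correction). Unfolded protein response genes had 1 and 6 of 19 (9.65th percentile, or 0.245 after input correction). The counts were 1 and 1 of 16 for p53 targets (55.1st percentile) and 3 and 6 of 50 for ribosomal protein genes (51.52nd percentile). The 3 higher ribosomal genes, RPL35, RPL7A and RPL12, lie on chromosome 9. Their log2 fold changes were 0.56, 0.50 and 0.45, and 0.18, 0.08 and 0.08 after input correction. HSPA5, the higher unfolded protein response gene, also on chromosome 9, went from 0.50 to 0.12. Of the 4 higher PI3K genes, TSC1 and MAPKAP1, on chromosome 9, went from 0.50 to 0.08 and from 0.48 to 0.11. PHLPP2, on chromosome 16, went from 0.54 to 0.51. Leukocyte markers had 2 measured genes, CD8A (84.0 to 131) and SPI1 (22.6 to 18.6), and endothelial markers 0. With total-tag scaling, counts adjusted over the list alone equalled those over all genes in each list, for example 19 higher and 0 lower of 20 interferon genes. Camera passed 0 of 19 lists with total-tag scaling, with the preset or an estimated correlation, and 3 with TMM factors, namely the interferon list, the mesenchymal list, and the transforming growth factor and WNT list. The fry test, which does not compare a list with other genes, passed 19. Median and camera direction differed in sign for the HOX, endometrial, H3K27 enzyme, PI3K and ribosomal lists, and median and mean for the H3K4 enzyme, m6A and cholesterol lists.

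Peaks present in both KD libraries and neither control library numbered 2176 for H3K4me3, against 260 present in control alone. The other 2 ways to split the 4 libraries gave 139 to 150. Gained regions had a median normalized tag count of 18.3, against 195.5 in shared regions. Of them 90.0% lay more than 1 kb from any end of a protein-coding gene, against 90% of lost and 42.85% of shared regions. An H3K27ac region overlapped 83.0% of gained regions, against 90% of lost and 91.89% of shared regions. The gained promoters with the highest values, KIF20A with BRD8, ZNF654 with LOC128031834, USF3 and HACD2, all had a control peak within 268 bp. The lost ones, POLR2L with TSPAN4, PLAG1 with CHCHD7, IER5L and VAV2, had a KD peak within 338 bp. A change in where a peak was placed is enough to list such promoters. Among regions with no peak of the other line within 5 kb (1700 gained, 179 lost), the following were chosen after their values were seen. H3K4me3 appeared at STING1, encoding an adaptor of cytosolic DNA sensing (46.0 normalized tags in KD), at SMOC2 (33.3), at LOXL2, a lysyl oxidase gene (30.1), and at IFI44, an interferon-induced gene (29.9). It was lost at STK32A, a kinase gene (142 in control), at LCP1, encoding the actin-bundling protein plastin 2 (40.9), at HS3ST5 (36.7) and at TWIST2, a mesenchymal transcription factor gene (17.95). A line without a peak has an unknown level, not 0. Without KD library 2, gained regions came to 3320. Without control library 1 or 2 or KD library 1 or 2, lost regions came to 664, 649, 412 and 417.

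H3K27ac changed in both directions, with more regions lower than higher in KD. The promoter of ITGB2, encoding the beta-2 integrin subunit, rose from 45.9 to 149 normalized tags (chromosome 21, 44927686 to 44928718, log2 fold change 1.68 ± 0.08, or 1.31 after input correction). Smaller rises were at MYADM (100.8 to 156, 0.63 ± 0.06), at the promoter of CCDC40 and TBC1D16 (0.61 ± 0.08), and at ARL14EPL (0.60 ± 0.06), ACSM6 (0.59 ± 0.08), LRIF1 (0.58 ± 0.07) and ZNF274 (0.57 ± 0.07). Falls were at SCEL, encoding sciellin of cornified epithelia (121 to 53.9, -1.15 ± 0.08), TMTC2 (93.9 to 41.8, -1.15 ± 0.09) and the potassium channel gene KCNJ16 (135 to 63.8, -1.07 ± 0.08). Others were at the peptidase gene DPP4 (84.9 to 42.8, -0.97 ± 0.09), DCDC2 (-0.95 ± 0.09), WNT7A, a WNT ligand of the female reproductive tract (100 to 51.7, -0.94 ± 0.08), and SNTB1 (-0.93 ± 0.09).

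Of 30135 regions with an H3K27ac peak in all 4 libraries, 4316 were higher and 11521 lower by limma-trend with Benjamini-Hochberg adjustment, around a median log2 fold change of -0.14. Removing that shift with TMM factors gave 6864 higher and 6337 lower, and DESeq2 on recovered tags 2066 and 1866. At 10049 protein-coding promoters the counts were 458 and 4631, or 1114 and 1666 relative to the shift. Peaks held 19.5% and 19.5% of tags in control and 17.9% and 17.8% in KD, in 40970 and 41036 peaks against 42418 and 42137.

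In several fixed gene lists more promoters fell than rose, as they did among all promoters. The epithelial and glycolysis lists passed camera downward with the preset correlation but not with an estimated one, and the epithelial list did not pass with TMM factors (adjusted p = 0.08148). Of 18 epithelial genes 0 rose and 12 fell, or 0 and 7 relative to the shift (2.15th percentile). The tight-junction gene CLDN3 went from 77.3 to 48.0 (-0.68 ± 0.09), the polarity gene CRB3 from 100.55 to 63.5 (-0.66 ± 0.08) and EPCAM from 113 to 78.8 (-0.52 ± 0.07). Among 18 glycolysis and hypoxia genes 13 fell and 0 rose, or 5 and 0 relative to the shift (3.04th percentile). The hexokinase gene HK2 went from 75.3 to 44.5 (-0.74 ± 0.09), ANKRD37 from 82.1 to 50.1 (-0.70 ± 0.09) and NDRG1 from 170 to 128 (-0.41 ± 0.06). Of 7 endometrial and Mullerian duct genes 4 fell and 0 rose, or 3 and 0 relative to the shift (4.37th percentile). The 3 were WNT7A, SOX17 (30.5 to 13.6, -1.10 ± 0.15) and MSX1 (-0.48 ± 0.13). Of 16 unfolded protein response genes 11 fell and 1 rose, or 5 and 3 relative to the shift (1.72nd percentile). CHAC1 had -0.35 ± 0.06 and XBP1 -0.29 ± 0.05. Of 10 inflammatory genes 7 fell and 2 rose, or 2 and 2 (6.97th percentile). The chemokine gene CCL20 went from 151 to 100 (-0.59 ± 0.06) and BIRC3 from 51.5 to 31.7 (-0.69 ± 0.11). Of 6 mesenchymal genes 4 fell and 0 rose, or 1 and 0 (42.28th percentile), TWIST2 going from 46.0 to 21.4 (-1.07 ± 0.12).

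Interferon and cell cycle promoters lay above other promoters, although in both lists more genes fell than rose. Camera passed both lists with the preset correlation (adjusted p = 0.0186 each) and neither with an estimated one (0.583 each). The median of 23 interferon genes was 0.21 above that of all promoters, higher than in all 10000 matched random lists. Of the 23, 4 rose and 6 fell, or 11 rose and 2 fell relative to the shift. TLR3 rose from 41.8 to 56.5 (0.43 ± 0.10), whereas the RNA sensor gene RIGI (-0.45 ± 0.08) and its adaptor gene MAVS (-0.41 ± 0.08) fell. Of 29 cell cycle and replication genes 7 rose and 8 fell, or 9 and 4 relative to the shift (99.76th percentile). The proliferation marker gene MKI67 went from 60.2 to 80.4 (0.41 ± 0.09), while the cyclin D1 gene CCND1 (-0.42 ± 0.06) and the inhibitor gene CDKN1B (-0.35 ± 0.08) fell. Of 13 HOX cluster genes 0 rose and 5 fell, or 5 and 3 relative to the shift (99.28th percentile, camera adjusted p = 0.559). Of the 5, 3 genes share 1 region, which the percentile counts 3 times. Values included HOXD8 at -0.56 ± 0.12. Of 3 pluripotency genes 1 rose, KLF4 (0.19 ± 0.08), which had -0.18 after input correction. That correction took the percentile of the list from 98.94 to 52.95.

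The remaining lists lay between the 24.68th and 90.63rd percentiles. After input correction the ribosomal list lay at 4.45, the H3K4 methylation list at 9.035 and the H3K27 enzyme list at 9.79. The others lay between 34.6 and 90.68. H3K4 methylation genes had 0 higher and 10 lower of 19, or 0 and 4 relative to the shift (24.75th percentile), including KMT2C (-0.66 ± 0.15) and KMT2A (-0.47 ± 0.11). H3K27 acetylation and methylation genes had 1 and 10 of 15, or 1 and 1 (31.22nd percentile), with EZH2 at -0.35 ± 0.08 and BRD3 at 0.42 ± 0.09, or -0.05 after input correction. Writers, erasers and readers of m6A had 0 and 11 of 19, or 0 and 1 (32.57th percentile), with YTHDF2 at -0.35 ± 0.08. The counts were 2 and 10 of 23 for PI3K-AKT-mTOR genes (3 and 4 relative to the shift, 49.19th percentile), with PIK3R1 at -0.53 ± 0.09, and 2 and 8 of 17 for cholesterol synthesis (2 and 2, 52.41st), with MVD at -0.67 ± 0.07. For immediate-early genes they were 4 and 6 of 14 (5 and 3, 90.63rd), with JUND at -0.59 ± 0.08. They were 1 and 7 of 16 for p53 targets (2 and 2, 70.21st), with a region at 1 end of XPC, next to TMEM43, at 0.43 ± 0.05 and BAX at -0.49 ± 0.09, and 1 and 28 of 48 for ribosomal proteins (5 and 5, 24.68th). Counts of 2 and 2 of 10 held for transforming growth factor and WNT targets (2 and 1, 85.97th), with ID2 at -0.52 ± 0.09 and ID3 at 0.44 ± 0.13. Of the leukocyte markers 1 was measured, CD8A (19.3 to 24.4), and of the endothelial markers 0. Adjusted over the list alone, 11 H3K27 enzyme genes and 14 glycolysis genes fell and 2 pluripotency genes rose. The other lists had equal counts. Camera with a preset correlation passed 4 lists, interferon and cell cycle upward and glycolysis and epithelial downward. It passed 0 with an estimated correlation (adjusted p = 0.583 with an estimated correlation for each of the 4), and fry passed 13. The median and mean of the ribosomal and PI3K lists lay on opposite sides of the all-promoter value. Of the PI3K genes higher relative to the shift, TSC1 and MAPKAP1, on chromosome 9, had -0.27 and -0.30 after input correction. PHLPP2, on chromosome 16, had 0.37.

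**Figure D2:**
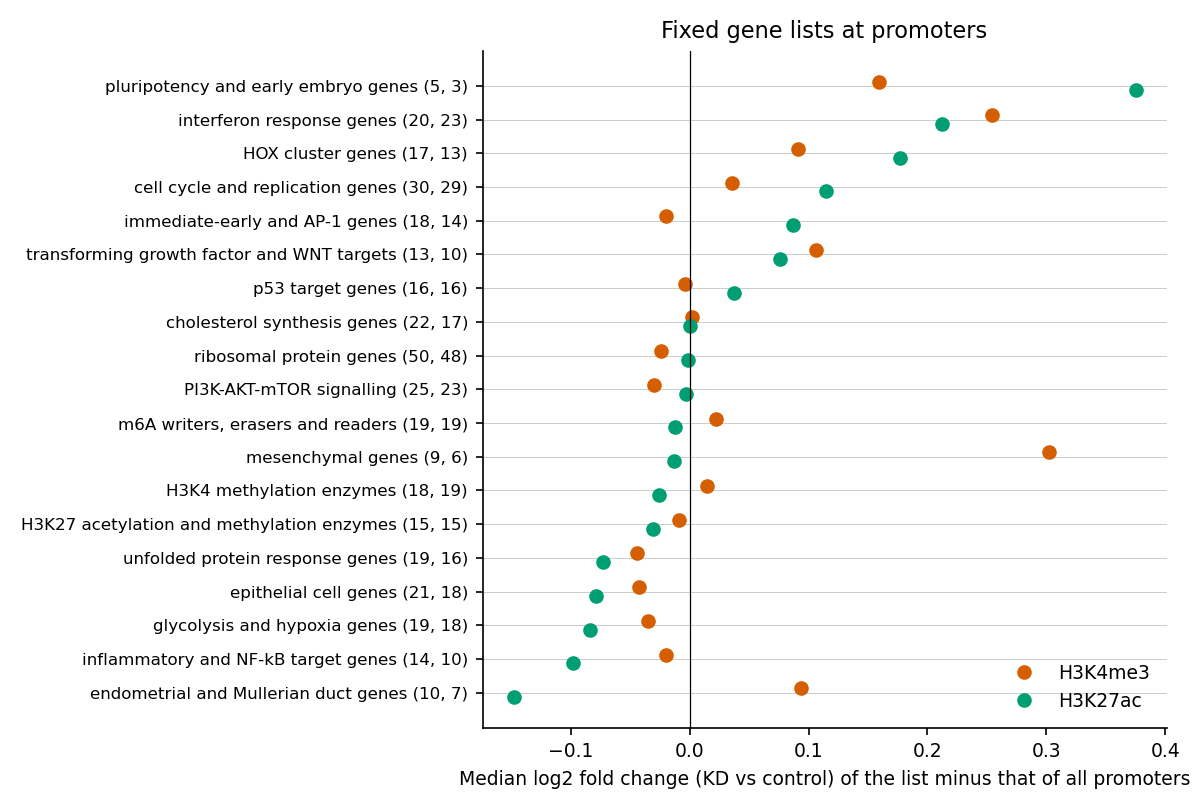
Median log2 fold change (KD vs control) of each fixed gene list at promoters minus that of all promoters, for H3K4me3 and H3K27ac. Interferon response genes lie 0.25 and 0.21 above all promoters, and epithelial genes 0.04 and 0.08 below.

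Distal H3K27ac regions spread more widely around their median than promoters did. The rise of smallest p was 33660 bp from PCED1B on chromosome 12 (47270320 to 47272545), from 133 to 354 normalized tags (log2 fold change 1.407 ± 0.05). The region held 1 peak in control and 2 in KD, so the KD value sums a second peak, and per kb of peak the change was 0.407. With 1 peak per library, others were inside HECW2 on chromosome 2 (39.9 to 152, 1.91 ± 0.08), inside BAIAP2 near AATK on chromosome 17 (32.1 to 125, 1.93 ± 0.09), and inside HSF2BP near H2BC12L on chromosome 21 (45.9 to 140, 1.59 ± 0.08). The fall of smallest p was 155267 bp from LY86 on chromosome 6 (6810249 to 6812939), from 366 to 107 (-1.77 ± 0.05). Others were 66199 bp from KLF6 on chromosome 10 (346 to 111, -1.63 ± 0.05), 166255 bp from HMGA2, a chromatin protein gene on chromosome 12 (249 to 68.5, -1.85 ± 0.06), and inside CMTM7 on chromosome 3 (417 to 179, -1.22 ± 0.04). Each of these 4 held 2 peaks in control and 1 in KD, and per kb of peak the changes were -0.77, -0.634, -0.845 and -0.217. The lines differed in this way in 34 shared H3K27ac regions.

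The 8772 promoter regions, which lay within 1 kb of an end of a protein-coding gene and overlapped an H3K4me3 peak, had a median log2 fold change of -0.19 with an SD over regions of 0.245. The 20771 distal regions had a median of -0.10 and an SD of 0.482, which includes counting error. Among promoter regions 429 were higher and 4032 lower, and among distal regions 3806 and 7297. Relative to the shift, 544 distal regions were higher and 521 lower by at least 2-fold, against 29 and 13 promoter regions. Distal regions can overlap an H3K4me3 peak, and 9551 of the 20771 did not. Among those 9551, 200 were higher and 311 lower by at least 2-fold relative to the shift. Distal peaks held 64.9% and 65.0% of in-peak tags in control and 65.7% and 65.9% in KD.

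Gained and lost H3K27ac regions were about equally many, 3371 and 3264, against 534 to 573 for the other splits of the libraries. Of these 92.8% and 95.3% were distal. The strongest gained promoters, TCEA1, SH2D6, UBAP2L with LTAP1, and ZFC3H1 with THAP2, had a control peak within 578 bp. Lost promoters with strong signal included RNF145, PLS3 and FASN, which had a KD peak within 363 bp. With no peak of the other line within 5 kb, 1977 regions were gained and 1986 lost. The genes named next were chosen after their values were seen. Their peaks lie within 1 kb of either end of the gene and, unlike promoter regions, did not have to overlap an H3K4me3 peak. They may therefore lie at 3' ends and cannot be read as promoters. Gained peaks stood at an end of TPRG1 (76.4 normalized tags in KD), of DKK1 (31.8) and of RELA, encoding an NF-kB subunit (26.9). The DKK1 peak (52318021 to 52319036) lies apart from the DKK1 region in which H3K4me3 rose (52313789 to 52314955). Lost peaks stood at SIRPB1 (75.7 in control), CD24, a cell-surface glycoprotein gene (33.1), the cytokine gene IL1A (31.0), the Notch target HEY1 (27.3) and the chemokine receptor gene CXCR4 (22.8). LCP1, NUPR1 and STK32A lost peaks of both marks. Leaving out KD library 1 or 2 raised gained regions to 6751 and 6907, and leaving out control library 1 or 2 raised lost regions to 5842 and 5821.

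The marks moved together at promoters. Across 8080 promoters with both marks, the log2 fold changes had a Pearson r of 0.587 and a Spearman rho of 0.421, across genes, which are not independent replicates. Relative to the shifts, 871 promoters were called in both marks, of which 456 were higher in both and 369 lower in both, against 104.6 and 172.2 for independent lists. The remaining 46 moved in opposite directions. These calls were made without correction for input, and parts of some chromosomes were higher in both marks and in the inputs, as described below. Some of the 456 may reflect that shared rise, and how many was not tested. With input correction the Pearson r was 0.542. The genes below are a selection among those with large joint changes and were chosen after their values were seen. Higher in both marks were MLKL, the effector of necroptosis (H3K4me3 45.8 to 186 normalized tags, log2 fold change 2.02 ± 0.08; H3K27ac 12 to 40.5, 1.67 ± 0.14), RBM23 (65.7 to 237 and 32.9 to 87.9), and the mechanosensitive channel gene PIEZO1 (105 to 334 and 34.1 to 75.6). So were ITGB2 (27.9 to 74.7 and 45.9 to 149), the glutamine synthetase gene GLUL (121 to 312 and 15.4 to 36.2), and the retinoic acid receptor gene RARG (98.6 to 226 and 25 to 48.1). SOCS3, encoding a feedback inhibitor of cytokine signalling (85.2 to 207 and 27.2 to 44.0), and GBP1, an interferon-induced GTPase gene (45.3 to 97.9 and 37.9 to 58.4), also rose in both.

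Lower in both marks were SCEL (H3K4me3 127 to 33.7, log2 fold change -1.92 ± 0.10), the lipoprotein receptor gene VLDLR (269 to 171 and, for H3K27ac, 54.8 to 17.8), and KCNJ16 (60.2 to 39.2 and 135 to 63.8). The same held for AHNAK2 (119 to 78.0 and 35.3 to 14.3), SPON1 (193 to 140 and 53.4 to 16.9), TMEM233 (111 to 64.1 and 35.1 to 11.2), MVP, encoding the major vault protein (194 to 162 and 61.1 to 28.7), and SOX17, a transcription factor gene of the endometrial epithelium (130 to 90.8 and 30.5 to 13.6).

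**Figure D3:**
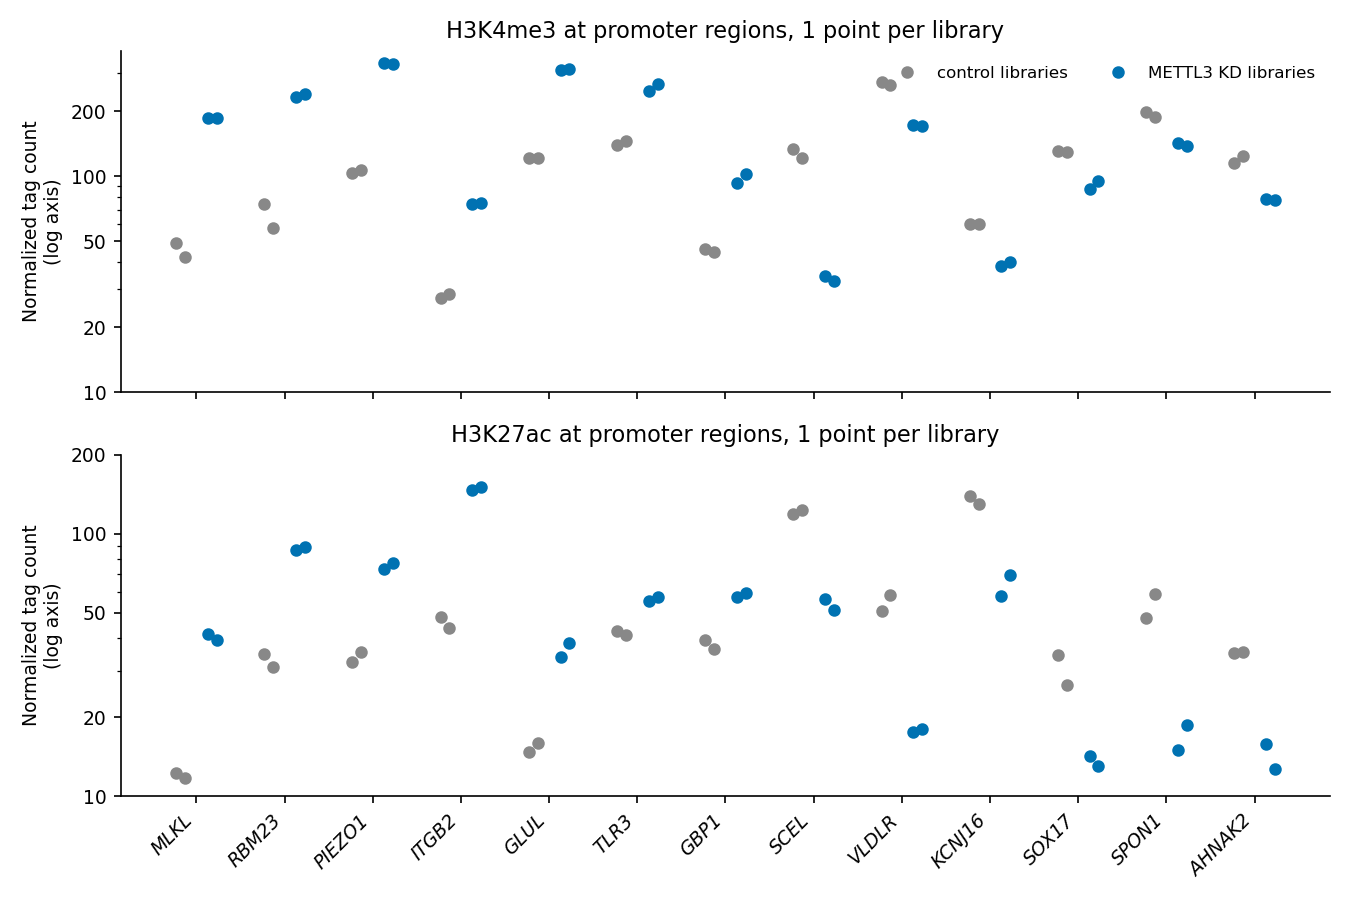
Normalized tag counts (log axis) of H3K4me3 and H3K27ac at 13 promoters chosen after their values were seen, 1 point per library for the control and METTL3 KD lines. MLKL rises from 45.8 to 186 in H3K4me3 and SCEL falls from 127 to 33.7, with the points of each pair close together.

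Parts of chromosomes 9 and 21 were higher in both marks and in the inputs. Regions on chromosome 9 from 60 Mb exceeded the median of all regions by 0.27 for H3K4me3 and 0.32 for H3K27ac, and regions on chromosome 21 by 0.25 and 0.31. Genes named above on these segments include ANXA1, QNG1, WDR5, BRD3, KLF4, ITGB2, MX1 and PFKL. After correction for input the excess was -0.11 and -0.03 on chromosome 9 and -0.03 and 0.04 on chromosome 21. Single genes elsewhere also moved with the correction, since input differed within other chromosomes too. For H3K4me3, THRB went from 0.72 to 0.59, NSUN2 from -0.15 to -0.01, and VLDLR, on chromosome 9 before 60 Mb, from -0.65 to -0.50.

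**Figure D4:**
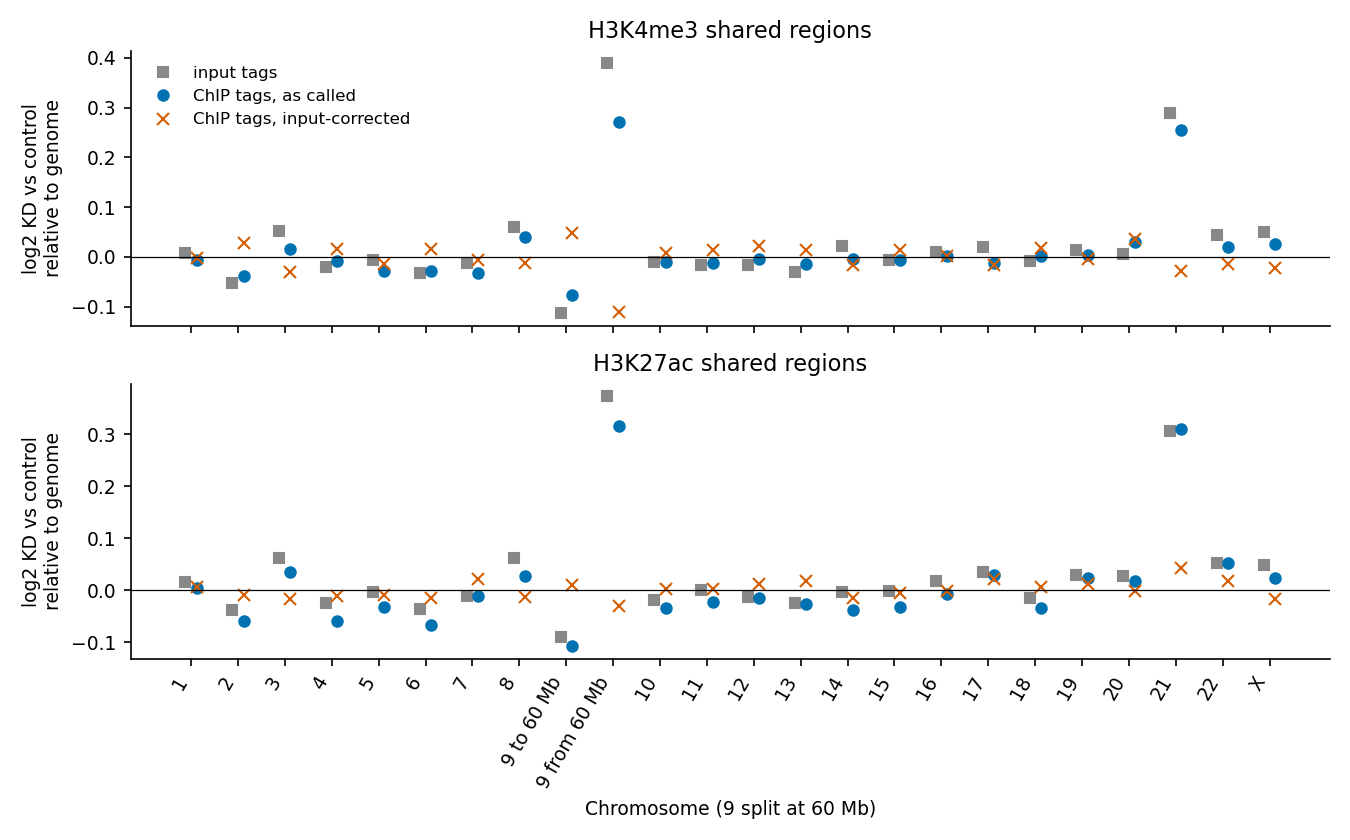
Log2 difference between KD and control, relative to the genome, of input tags and of ChIP tags before and after correction for input, by chromosome, with chromosome 9 divided at 60 Mb. The input squares of chromosome 9 from 60 Mb and of chromosome 21 stand at 0.29 to 0.39, apart from the other 22 segments, which lie between -0.113 and 0.0628. Only chromosome 9 was divided, so input differences within other chromosomes are averaged out here.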

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

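The tests of a single yield factor, of the amount of fly chromatin and of copy number were chosen after the results were seen; the threshold test was set before its result.

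Fly sequences, from chromatin added before the immunoprecipitation, gave a signal in the H3K4me3 lists that the comparisons do not use. Tags in fly peaks came to 2528 and 2580 in the control libraries and 450 and 405 in the KD libraries, in 55, 58, 10 and 9 peaks. No H3K27ac list held a fly peak. In the 6 fly regions called in all 4 libraries the tags were 390 and 389 against 297 and 289, a log2 ratio per total tags of -0.37 (95% interval -0.53 to -0.21), while H3K4me3 on human regions rose by a median of 0.29.

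A single yield factor, equal for all regions of the KD libraries, can be neither accepted nor rejected as the whole cause. The median log2 fold change over 5 equal groups of regions by level ranged by 0.163. From the weakest to the strongest group it was 0.27, 0.42, 0.34, 0.28 and 0.25. The range cannot decide, since its limit was set after the values were seen. Regions also had to hold a peak in all 4 libraries, which can shift the medians of weak groups. A difference in yield or enrichment that varies with the level of a region stays possible as well. Whether weak regions passing the peak threshold are the whole cause of the gained regions is not decided. After dividing KD values by the weak-region ratio of 1.275, 1080 of 2176 gained regions still lay above the control threshold. That was 4.15 times (3.63 to 4.76) as many as the 260 lost regions. All 260 lost regions passed, since the control threshold (14.4) already lay above that of KD (13.85), so that count was not put to a test. Gained regions were picked for high KD values, so scatter around the median ratio alone leaves some above. Of the gained regions 476 also had a control peak within 5 kb. Less fly chromatin in the KD samples may explain the fly tags: input tags in the same 6 regions had a log2 ratio of -0.59 (-1.06 to -0.13), but without the region that held most of them only 13 and 5 tags were left (-1.36, -3.2 to 0.22). With so few tags, and with input tags in human regions also lower in KD, less chromatin and a lower yield cannot be told apart. A rise of H3K4me3 that follows METTL3 depletion stays open and untested, as does its size, because 1 sample per line cannot separate the lines from their preparation.

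In the inputs, against which the authors called peaks, tags per total in the regions of both marks were lower in KD on 22 segments (log2 ratios of -0.313 to -0.139), for reasons not tested, and higher on 2. Relative to the other segments, input tags on chromosome 9 from 60 Mb were higher in KD by 0.389 (log2) in H3K4me3 regions and 0.373 in H3K27ac regions, and on chromosome 21 by 0.289 and 0.306. More copies of these segments in the KD line may explain why both marks are higher there: in each pair of inputs the lower of the 2 segments exceeded the highest other segment by at least 0.18. A rise of the marks beyond copy number is argued against, since the largest excess left after correction for input was 0.043; H3K4me3 on chromosome 9 from 60 Mb was then at -0.11 relative to the median of all regions, so it rose less than its input, and why stays open. Input tags were available only inside peaks, and whether the difference arose with the knockdown or with the choice of cells for the stable lines was not tested.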

How the results depend on the processing

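The number of called regions depended on the scaling and on the peak threshold. For H3K4me3, 14297 higher and 306 lower regions became 3193 and 2040 with TMM factors and 1468 and 398 with DESeq2. TMM and DESeq2 remove the shared shift by construction. Scaling by fly tags, chosen after seeing the data, gave 16468 and 74. At 8-fold over input 77 were lower, with 11820 regions tested. For H3K27ac, 4316 higher and 11521 lower became 6864 and 6337 with TMM factors, 2066 and 1866 with DESeq2, and 588 and 3748 at 8-fold over input (7195 regions tested). They became 6524 and 6001 with edgeR on recovered tags and TMM factors, added later; edgeR on recovered tags without them gave 4113 and 11130. The minimum of 50 tags, tags per kb, 1 peak per region, the pseudocount, input correction and leaving out chromosomes 9 and 21 or any 1 library kept these counts within 1.5 times. The replicate block gave 14298 and 308 for H3K4me3 and 4310 and 11477 for H3K27ac. Same-numbered libraries did not deviate together (correlations of -0.0065 and -0.0052), so the numbers do not pair the libraries. Gained and lost H3K4me3 regions came to 710 and 29 at 8-fold, and to 3022 to 3320 and 412 to 664 without 1 library. H3K27ac regions came to 1017 and 726 at 8-fold, 1977 and 1986 with no other-line peak within 5 kb (added later), and 4760 to 6907 and 4421 to 5842 without 1 library, since fewer lists must then hold or lack the peak. At 8-fold the KD minus control difference was 7.92 percentage points of tags in peaks and 1280 peaks for H3K4me3, and -0.735 points and 665.5 peaks for H3K27ac. Lists past the threshold numbered 0 for H3K4me3 in camera, 19 with fry, which does not compare a list with other genes, 3 with TMM factors and 0 to 2 without 1 library (2 without KD library 1). For H3K27ac 4 became 0 with an estimated correlation, 13 with fry, and 3 with TMM factors (without the epithelial list), with the 2.5 kb window and without either control library. Promoter minus distal H3K27ac stayed negative, at -0.0896 to -0.0717 without 1 library. The correlation of the marks fell from 0.587 to 0.542 with input correction, added later, and to between 0.534 and 0.560 without 1 library. Among named genes called in the main fit, signs turned under fly scaling at NSUN2 and SRD5A1 (0.22), ICE1 (0.24), and CCT5 and ATPSCKMT (0.27); with input correction at ICE1 (0.011) for H3K4me3 and at BRD3 (-0.052) and KLF4 (-0.18) for H3K27ac; and with TMM factors and DESeq2 alike, for H3K4me3, at MYC (-0.001), EDEM1 (-0.050) and METTL3 (-0.072). With DESeq2, 42 of 79 named H3K27ac results and 24 of 71 named H3K4me3 results kept their sign but were no longer called. With TMM factors this held for 10 of 80 and 10 of 71, while 2 and 1 became called. Except where a setting's construction is named, the cause was not tested. Small changes are missed more often: in simulated data 57% of H3K27ac changes of 0.5 (log2) were recovered, against 96% of changes of 1.0.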

Other observations

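The interferon list without chromosomes 9 and 21 was tested as set before its result; all genes and regions below were chosen after the values were seen.

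Distal H3K27ac regions near some genes changed mostly in 1 direction, counted relative to the shift of all regions. The genes were picked for having several such regions, and no chance count was made. Near TGFB2, a transforming growth factor ligand gene, 7 of 7 distal regions were higher in KD and 5 further regions were gained, with a median log2 fold change of 1.23. All 9 regions near the metalloprotease gene ADAMTS15 were higher (median 0.84), as were 6 of 6 near the tetraspanin gene CD9 (0.81), with 1 gained and 1 lost. Near THRB 6 of 8 were higher and 1 lower, with 3 gained (0.74). Near IGFBP3 12 of 20 were higher and 3 lower, with 2 gained and 2 lost (0.41), and near TNS3, which encodes tensin 3, 20 of 38 were higher and 4 lower, with 6 gained (0.30). Relative to the shift, H3K4me3 at the promoter was also higher at IGFBP3 (0.43) and THRB (0.426), as it was for 1693 of 11091 genes. The distal calls were made without correction for input. On the lower side, 11 of 11 regions near F3, the tissue factor gene, fell and 8 more were lost (median -0.82), along with 11 of 14 near KLF6 with 4 lost (-0.46). Near the semaphorin receptor gene NRP1 10 of 14 fell and 1 rose, with 9 lost (-0.55). All 8 near KCNMB1 fell, with 7 lost (-0.76), and 5 of 5 near CNTN6, with 1 lost (-1.31). The nearest gene is an assignment by distance, and no contact between region and gene was measured.

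Some promoters moved in opposite directions in the 2 marks relative to the shifts, 23 with H3K4me3 higher and H3K27ac lower and 23 the other way. FGFR4, a fibroblast growth factor receptor gene, went from 162 to 236 normalized tags in H3K4me3 and from 58.7 to 38.7 in H3K27ac. MYOF, encoding the membrane-repair protein myoferlin, went from 183 to 249 and from 137 to 105. HSPB6, a small heat shock protein gene, went the other way relative to the shifts, with log2 fold changes of -0.14 in H3K4me3 and 0.31 in H3K27ac, and HIPK1, a kinase gene, with -0.10 and 0.26. Without removal of the shifts both marks were higher in KD at HSPB6 and HIPK1 (0.15 and 0.17, and 0.20 and 0.12). These promoters are fewer than the 169.8 and 106.0 that independent lists of the same sizes would give. The calls were made without correction for input.

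Interferon response promoters lay above other promoters in both marks among matched random lists, which ignore correlation between genes, while camera gave adjusted p = 0.0734 for H3K4me3 and 0.0186 for H3K27ac. With an estimated correlation it gave 0.7755 and 0.583, so the list result is not firm. Extra copies of chromosomes 9 and 21 are argued against, because without the members there the median still lay at the 99.96th percentile of matched random lists or above in both marks. A rise that follows METTL3 depletion may account for it and stays open and untested, since no RNA was analysed here and 1 sample per line leaves other differences between the stable lines possible.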
